A study of Mus musculus with 95 samples.

How the data were processed

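Messenger RNA of pancreatic islets was measured in 95 libraries. Per the labels' protocols, RNA was extracted with a column kit that included a DNase step, control transcripts of the ERCC mix were spiked in, and libraries were made from RNA captured by its poly(A) tail. The deposited count table holds estimated counts for 20638 genes, with no normalization: 67.7% of its cells were whole numbers to within 1e-6, and the others were fractions. The submitters' processing notes name the mouse genome build GRCm38 and the tool DESeq2, without saying what each was used for. The aligner, the counting tool, its use of strand and the annotation release were not given in the sources used here, and the version of DESeq2 was not given either. A second deposited table holds variance-stabilised values for the same genes and libraries, on a scale close to log2. Its lowest value, 6.45, was shared by all 95 libraries. Another table from the authors gives each gene's symbol and position. By Ensembl identifier, 20532 genes matched the GENCODE release M21 annotation of GRCm38, and 16528 had the same start and end there. Coordinates are given as the authors' table has them, and the kind of gene was taken from GENCODE. The count table held 0 rows for the ERCC controls, so library totals were formed from mouse genes alone.

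The labels give the tissue and a diet of 45% fat for every library and give neither strain nor sex per library. All 95 libraries were therefore left unassigned to groups, no comparison between groups was made, and values are given as medians and ranges over the libraries. Each library is called by the number in its label. All columns of the tables were used. Estimated counts were rounded to whole numbers before dispersion estimates. Expression levels were computed as CPM, counts scaled to a common library total, with library sizes adjusted by the trimmed mean of M values (TMM) in edgeR 4.0.16, whose factors ran from 0.46 to 1.29. The log2 CPM used a prior count of 2. A low-count filter kept genes with a CPM of 1 or more in at least 10 libraries, which left 15841. For each kept gene the biological coefficient of variation, the square root of edgeR's gene-wise dispersion with only an intercept in the model, was estimated, and genes above 50% were counted. It holds strain, sex, litter and technical differences together.

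Lists of 22 gene groups, markers of other cell types among them, were fixed before the data were examined. The coherence of a list was the mean pairwise Spearman rho of its kept members over the libraries. It was compared with 10000 random lists of the same size, matched on mean expression in 10 classes, in an upper one-sided test with Benjamini-Hochberg adjustment over the 21 lists with 3 or more kept members. A list score was the mean of its members' z-scored log2 CPM. The 18 relations between scores, fixed at the same time, were tested with Spearman's rho and Pearson's r by two-sided permutation tests of 100000 resamples each, adjusted by Benjamini-Hochberg over the 18. Genes held by both lists of a pair were left out of both scores. A score with an empty stretch of over 20% of its range and at least 6 libraries on each side was to be called clustered, and 0 of the relations met this. Genes are named in the text by a rule set beforehand: the 10 with the highest median CPM, the 15 with the widest range from the 10th to the 90th percentile of log2 CPM at a median of 1 CPM or more, the 10 with the lowest biological coefficient of variation at a median of 50 CPM or more, in each list the members with the highest median and the widest and narrowest ranges, and, for the closing section, the 10 genes with the largest gap between neighbouring sorted values plus Nnt, Xist, Ddx3y, Uty, Kdm5d and Eif2s3y. Some genes that meet the rule are not reported here. Gm28661, and the libraries and genes singled out among the other observations, were chosen after their values were seen.

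Sequence shared between genes was measured as the share of a gene's 31-base words found in the transcripts of another GENCODE M21 gene. The alternatives were size factors from DESeq2 1.42.0, no low-count filter, a prior count of 0.5, DESeq2 dispersions, the deposited variance-stabilised values, totals without the acinar and hormone lists, leaving out the 10 libraries with the lowest totals, removal of 5 principal components or of the acinar score, scores as medians, and libraries numbered 50 or lower and above 50 taken apart. A further 3 were added after seeing the data: circular shifts of a score along the library numbers, leaving out libraries numbered above 90, and leaving out the 9 libraries with over 25% of counts in the acinar list. The steps were tested on simulated counts with the real means and depths over 15841 genes, except the relations, which were tested on simulated normal scores. Of 200 genes given a coefficient of 80%, 200 were estimated above 50%, against 0 of 15641 given 20%. For list coherence, 20 of 20 lists with a shared factor and 1 of 20 unrelated lists were called. For relations, 93 of 100 related and 5 of 100 unrelated pairs were called. The simulated libraries were independent of each other, so these figures do not give the rate of false calls where neighbouring libraries are alike. Of 200 genes given levels 16-fold apart, 199 showed a gap of 1.5 log2 or more, against 0 of the others. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Library totals of 16411809 to 34357253 counts give narrow counting intervals. Wilson 95% intervals of shares treat every count as independent and do not cover the spread between libraries. PCR copies are not independent molecules, so these intervals are too narrow even for counting error.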

Results

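Gene expression was measured by RNA-seq in pancreatic islets, the clusters of hormone-secreting cells of the pancreas. The mice came from the founder strains of the Diversity Outbred population and were kept on a diet high in fat and sugar, given as 45% fat in the labels. The set held 95 libraries, numbered from 1 to 100 with 5 numbers missing. Strain and sex were not given per library, so the libraries formed 1 set and no groups were compared. Total counts ran from 16411809 in library 22 to 34357253 in library 38, with a median of 26552738. A median of 19613 genes had an estimated count of 1 or more. Among 4465 pairs of libraries the chi-square statistic per degree of freedom was 8.08 or higher, the lowest for libraries 25 and 26. It was 2 or lower in 0 pairs, so each library was counted separately. Nothing in the labels says that each came from its own animal, so p-values measure the spread between these libraries. That spread may hold strain, sex, litter and technical differences together, and libraries of the same strain are not independent of each other.

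Insulin transcripts were the most abundant in these islets. Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142699510, GRCm38) had a median of 112910 CPM and ranged from 35013 to 161803. Ins1 (chromosome 19, 52264323 to 52265456) had a median of 45421 CPM and ranged from 19315 to 66722. They were followed by Iapp, which encodes the amyloid polypeptide secreted with insulin, at a median of 13694 CPM, and Gcg, the glucagon gene of alpha cells, at 12923 CPM. The secretory granule proteins Chga and Scg2 had medians of 10528 and 6480 CPM. The digestive enzyme genes Ctrb1, Pnlip and Amy2a3 were also among the 10 most abundant, at medians of 8750, 5578 and 4820 CPM. The remaining gene was mt-Co1, a mitochondrially encoded subunit of cytochrome oxidase, at 5339 CPM. The 8 hormone genes together took a median of 19.7% of counts. Their lowest share was 6.82% in library 54 (95% Wilson interval 6.81% to 6.83%) and their highest 26.6% in library 46 (26.6% to 26.6%).

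The insulin genes varied less between libraries than the hormone genes of rarer endocrine cells. Ins1 spanned 0.57 log2 units from the 10th to the 90th percentile, and Ghrl, the ghrelin gene, 4.22 log2 units at a median of 1.75 CPM. Of the 8 hormone genes, 4 had a biological coefficient of variation above 50%: Sst (somatostatin, 54.7%), Ppy (pancreatic polypeptide, 55.9%), Pyy (peptide YY, 56.7%) and Ghrl (105%). Of the 17 beta cell identity genes 0 exceeded 50%, and their median was 26.0%. In that list G6pc2, the islet glucose-6-phosphatase subunit, was highest at a median of 2190 CPM. Glp1r, the incretin receptor, had the widest range at 1.31 log2 units and Kcnj11, the pore of the ATP-sensitive potassium channel, the narrowest at 0.52. The alpha cell list had a median coefficient of 48.7%, with 2 of 8 genes above 50%. The transcription factor gene Irx1 had its widest range, 2.04 log2 units, and the amino acid transporter gene Slc7a2 the narrowest, 0.81. All 4 delta cell genes exceeded 50%, with the widest range, 2.15 log2 units, for the retinol-binding protein gene Rbp4 and the narrowest, 1.88, for the ghrelin receptor gene Ghsr.

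Transcripts of acinar cells, which make the digestive enzymes of the pancreas, varied more between libraries than those of the endocrine lists. The 18 acinar genes together took a median of 5.86% of counts, from 0.214% in library 25 (0.212% to 0.216%) to 33.6% in library 54. All 18 had a coefficient of variation above 50%. The members spanned a median 42.1-fold between the 10th and 90th percentiles. Ctrb1, a chymotrypsinogen gene, ranged from 293 to 101602 CPM. The trypsin gene Prss2, with the narrowest range of the list, ran from 132 to 44940 CPM, and Prss1 had the widest at 8.18 log2 units. The 6 libraries with the highest acinar shares, 28.5% to 33.6%, held 6.82% to 11.6% of counts in hormone genes. The amylase genes Amy2a3, Amy2a4 and Amy2b share 100%, 100% and 56.4% of their 31-base words with their closest relative, and Prss1 54.8%, so their separate values are uncertain.

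**Figure D1:**
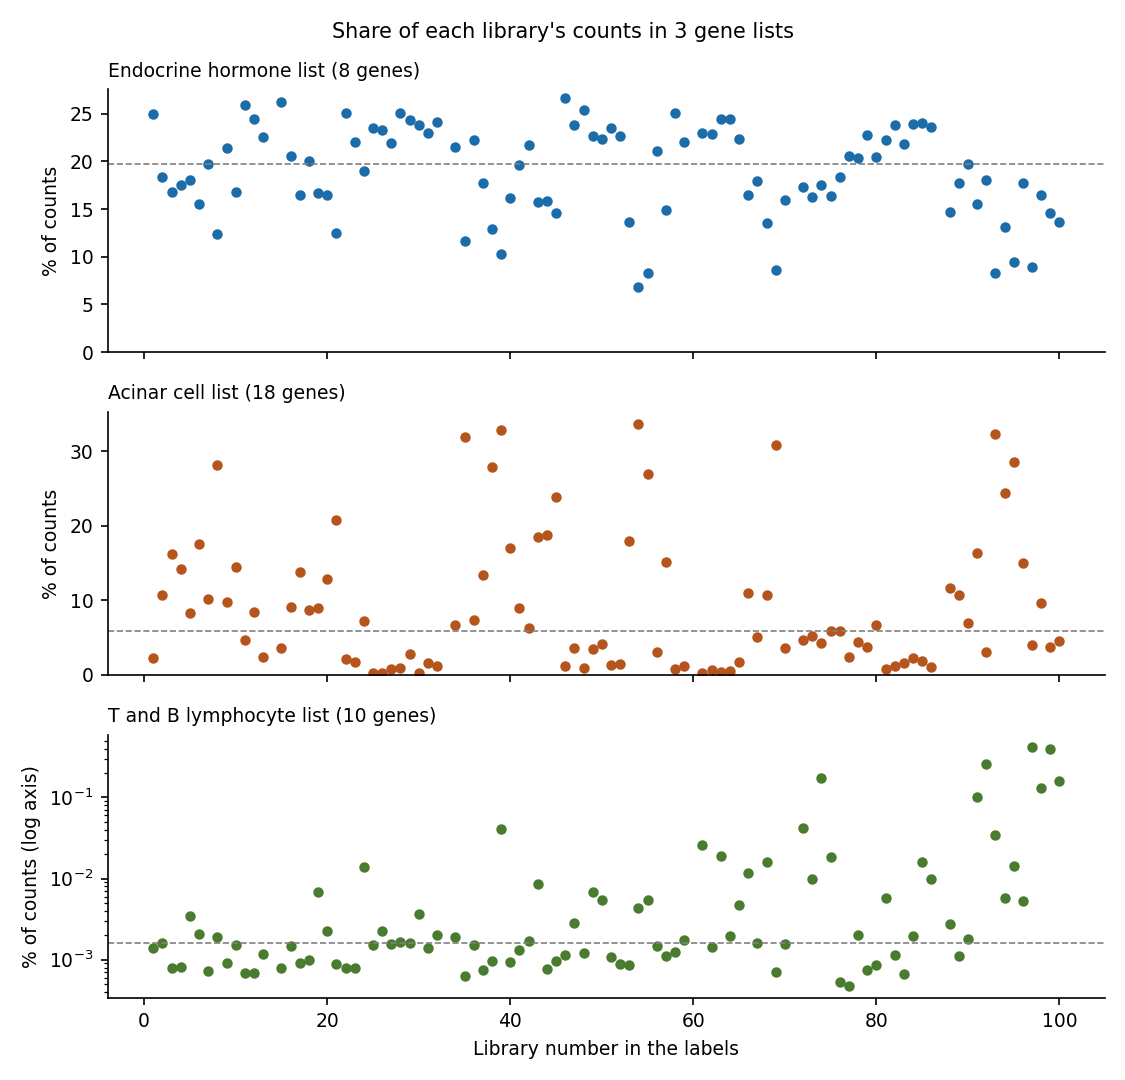
Percent of each library's counts in the endocrine hormone list (top), the acinar cell list (middle) and the T and B lymphocyte list (bottom, log axis) against the library number in the labels, 1 point per library, with the median over the 95 libraries as a dashed line. Acinar genes took from 0.214% to 33.6% of counts, and the lymphocyte list was highest, at 0.423%, in library 97.

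Other cell types that an islet preparation can hold were also seen. Among duct cell genes, 6 of 8 exceeded 50%: the keratin gene Krt7 had a median of 186 CPM and the narrowest range at 0.85 log2 units, and Tff2, which encodes a secreted trefoil peptide, spanned 5.24. The members had a median level of 15.6 CPM and a median range of 3.73 log2 units. Krt7 thus differed from most of its list, and which cells it came from was not tested. Of 9 endothelial genes 0 exceeded 50%. Plvap, which forms the diaphragms of fenestrated capillaries, was highest at a median of 173 CPM, and ranges ran from 0.66 log2 units for the receptor gene Tie1 to 1.28 for Tek. In the fibroblast and stellate list 8 of 10 genes exceeded 50%. The matrix glycoprotein gene Sparc was highest and least variable (median 121 CPM, 1.53 log2 units) and the growth factor receptor gene Pdgfra most variable (3.54). Of 4 glial genes 2 exceeded 50%. The transcription factor gene Sox10 had the widest range at 3.01 log2 units. The erythroid list took a median of 0.00501% of counts, with 4 of 5 genes above 50%. Its haemoglobin genes Hba-a1 (median 0.272 CPM) and Hba-a2 (23.4 CPM) share 75.4% and 92.6% of their words with each other, which leaves the division of their reads uncertain. Fabp4, a fatty acid-binding protein gene, was the only adipocyte gene kept of 6 fixed, at a median of 8.85 CPM.

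Most of the immune genes in the fixed lists varied widely between libraries. All 10 macrophage genes had a coefficient of variation above 50%. The complement gene C1qa was highest at a median of 24.8 CPM. Lyz2, the lysozyme gene, ranged from 3.11 to 1347 CPM, and the growth factor receptor gene Csf1r, with the narrowest range, from 6.97 to 164 CPM. Lyz2 shares 32.8% of its words with another gene, so its value is uncertain. The 10 T and B lymphocyte genes, all above 50%, took a median of 0.00163% of counts and 0.423% in library 97 (0.420% to 0.425%). Cd79a, with the narrowest range of the list, ran from 1.32 to 202 CPM. All 7 MHC class II genes exceeded 50%: Cd74, the class II chaperone, had a median of 131 CPM and a maximum of 3749, H2-DMa the narrowest range at 1.67 log2 units, and the beta chain gene H2-Eb1 the widest at 6.59. Of the MHC class I list 6 of 8 genes exceeded 50%. Its light chain B2m ranged from 27.9 to 1797 CPM, H2-K1 was the most abundant at a median of 210 CPM, and Tapbp, the peptide-loading factor tapasin, varied least at 0.87 log2 units.

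Genes of cell stress and division showed unequal spreads within their lists. Of 16 unfolded protein response genes 2 exceeded 50%. Hspa5, the main chaperone of the endoplasmic reticulum, had a median of 1443 CPM, and ranges ran from 0.56 log2 units for the co-chaperone gene Dnajc3 to 3.22 for the transcription factor gene Atf3. Immediate early genes, 3 of 10 above 50%, took a median of 1.07% of counts. Egr1 was highest at 2751 CPM and least variable at 1.43 log2 units, and the heat shock gene Hspa1b spanned 4.37, with 67.6% of its words shared with another gene. Of 15 proliferation genes 14 exceeded 50%. Mki67 had a median of 4.69 CPM and a maximum of 97.1 CPM in library 97, and ranges ran from 1.35 log2 units for the cell cycle regulator Foxm1 to 2.55 for the spindle checkpoint gene Bub1. Of 13 interferon response genes 12 exceeded 50%, with the chemokine gene Cxcl10 most variable (6.05 log2 units).

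Of 16 cholesterol synthesis genes 0 exceeded 50%. Ranges ran from 0.41 log2 units for Dhcr7 to 1.41 for Msmo1. Among genes normally kept low in beta cells, 8 of 10 exceeded 50%. The RNA-binding protein gene Zfp36l1 had the highest median at 24.8 CPM, and the hexokinase gene Hk1 the narrowest range at 0.97 log2 units. Aldh1a3, a retinaldehyde dehydrogenase gene, had the widest at 4.16 and a maximum of 220 CPM in library 90. The 13 mitochondrially encoded genes took a median of 1.85% of counts, and 2 exceeded 50%. Their ranges ran from 0.60 log2 units for mt-Co3 to 5.72 for mt-Co2, which share 99.9% and 99.5% of their words with nuclear copies, so both are uncertain. Other members share up to 99.5% of their words with another gene. The share of counts, the coherence and the relations of this list are therefore uncertain as well.

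**Figure D2:**
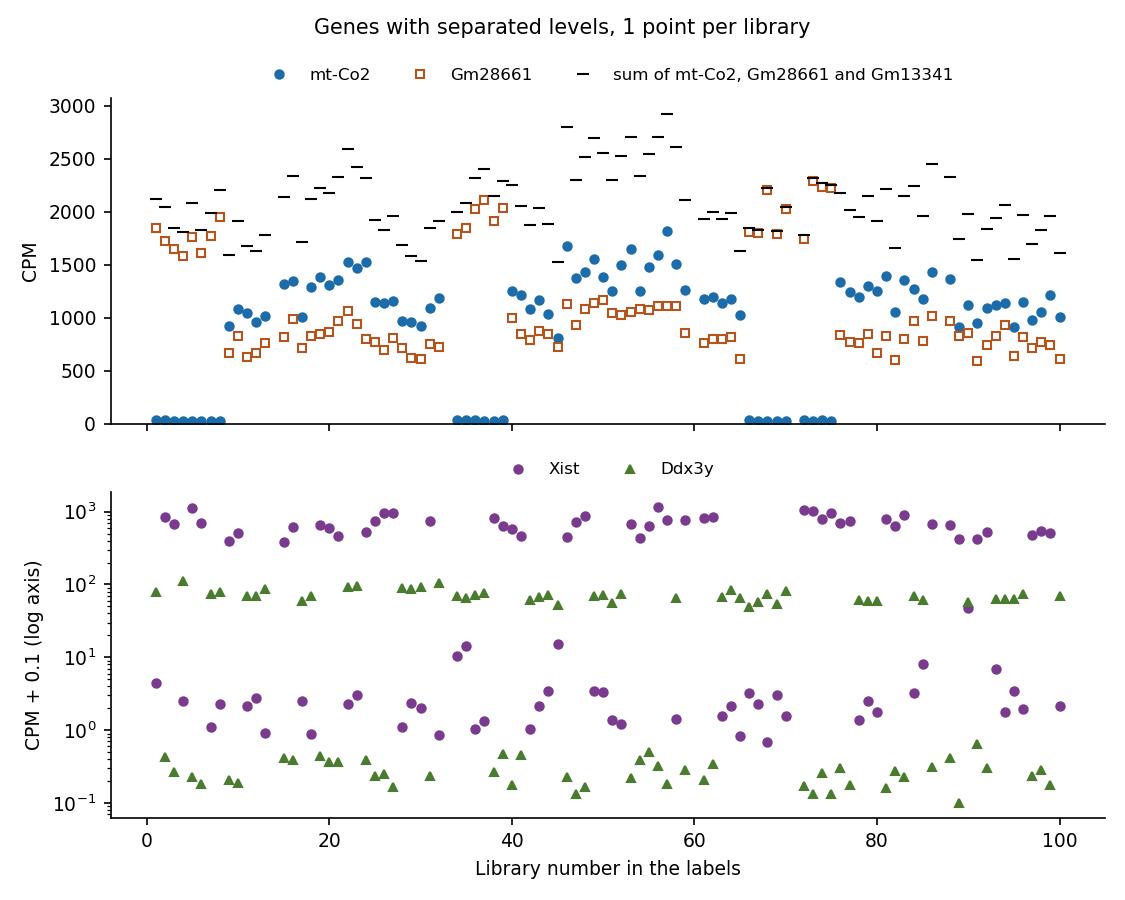
CPM of mt-Co2, of its nuclear copy Gm28661 and the sum of both with Gm13341 (top, linear axis), and CPM + 0.1 of Xist and Ddx3y (bottom, log axis), against the library number, 1 point per library. The mt-Co2 values ran from 22.6 to 1814 CPM, while the sum ran from 1527 to 2926 CPM.

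Over all kept genes, the median biological coefficient of variation was 26.1%, and 3880 of 15841 genes (24.5%) exceeded 50%, against 7713 of 20638 without the low-count filter. The genes with the widest ranges were pancreatic enzyme genes, pseudogenes, Xist and genes of immunity. After the pseudogene Gm15459 (12.26 log2 units) came Amy2a3 (12.20) and the protease gene Cela3a (9.78). Xist, the RNA that silences an X chromosome in females, spanned 9.40, the protease gene Ctrc 9.29 and Amy2a4 9.10. Rps3a2 (8.56), Gm13841 (8.42), H2-Ea-ps (8.35), Gm14648 (8.34) and Gm13835 (8.11) are annotated as pseudogenes, and Igha (8.45) encodes an immunoglobulin heavy chain. Reg2 (8.24), Prss1 (8.18) and Amy2b (8.15), which GENCODE lists as a pseudogene, are of the exocrine pancreas. Gm15459, Rps3a2, Gm13841, Gm14648 and Gm13835 share 84.8% to 100% of their words with another gene, Cela3a 45.8% and Ctrc 19.2%, so their values depend on how reads were divided. The most even genes, at a median of 50 CPM or more, were not tested for a shared function. They included the splicing factor gene Sf3b2 (5.74%), the ubiquitin-conjugating enzyme gene Ube2q1 (5.83%), the proteasome subunit gene Psmd11 (6.45%), Nap1l4 (6.52%) and the autophagy gene Becn1 (6.65%). Gak (6.69%) followed, with the mitochondrial peptidase gene Pmpca (6.73%), the deubiquitinase gene Usp8 (6.75%) and Arfgap2 (6.81%).

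Genes of the same list rose and fell together over the libraries for 20 of the 21 lists tested. The acinar list was most coherent, with a mean pairwise rho of 0.913 over its 18 genes against a median of 0.0466 in random lists. It was followed by the delta cell (0.746), proliferation (0.694), mitochondrially encoded (0.690), T and B lymphocyte (0.656), fibroblast and stellate (0.646), MHC class II (0.637) and MHC class I (0.627) lists. The erythroid (0.598), endothelial (0.597), macrophage (0.524), interferon (0.461), immediate early (0.434), cholesterol synthesis (0.40), unfolded protein response (0.362) and low-in-beta-cell (0.328) lists also passed. For these 16 lists the p was 0.0001, the smallest that 10000 random lists can give, and the adjusted p 0.000131. The alpha cell (0.323, adjusted p = 0.000247), duct (0.221, adjusted p = 0.000467), beta cell identity (0.254, adjusted p = 0.000995) and glial (0.305, adjusted p = 0.0162) lists passed as well. The endocrine hormone list, whose genes belong to different cell types, had a mean rho of 0.128 and did not pass (adjusted p = 0.130). The beta cell identity, duct and glial lists did not pass among libraries numbered 50 or lower (adjusted p = 0.276, 0.0679 and 0.220), nor glial genes above 50 (0.242) or beta cell identity genes without libraries numbered above 90 (0.0808). The macrophage list passed at a lower 0.175 among libraries numbered 50 or lower, and the lymphocyte and low-in-beta-cell lists at 0.330 and 0.164 with 5 principal components removed. Over all alternatives the endothelial, alpha cell and MHC class II lists fell to 0.333, 0.188 and 0.403 at the lowest, and still passed. With the acinar score removed the duct list missed the threshold (0.0553) and the hormone list passed it (0.0338), as the hormone list did with 5 principal components removed (0.0407).

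**Figure D3:**
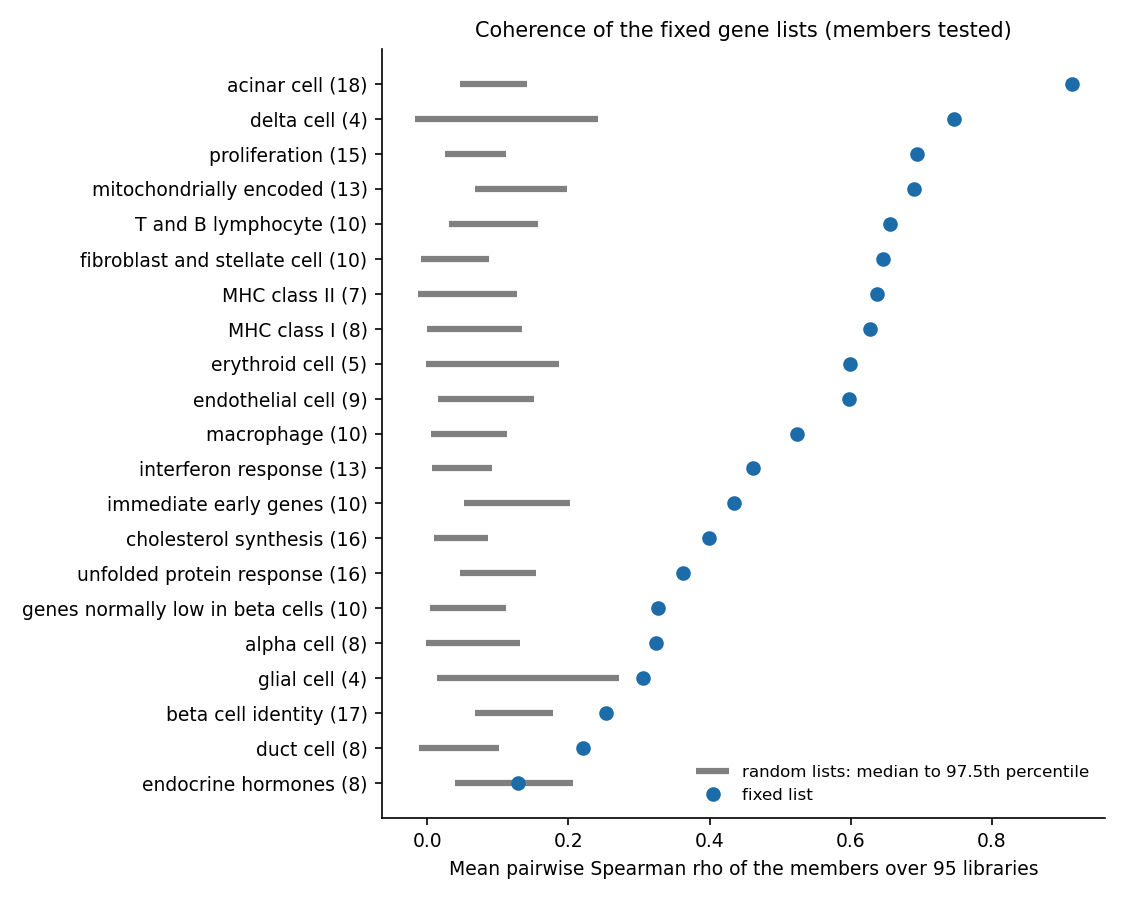
Mean pairwise Spearman rho of the kept members of each fixed list over the 95 libraries (points; number of members in parentheses), with grey bars from the median to the upper end of the central 95% of 10000 random lists matched on expression. The acinar list reached 0.913 and the endocrine hormone list, at 0.128, lay inside its random range.

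Libraries with more acinar transcripts held more duct cell transcripts and lower scores of hormone genes. The acinar and duct scores rose together (rho = 0.809, p = 1e-05, adjusted p = 2.57e-05; r = 0.785, p = 1e-05, adjusted p = 1.80e-05). Without the 2 libraries farthest from the median, 25 and 54, r was 0.775. A p of 1e-05 is the smallest the permutations can give, and each adjusted p of 2.57e-05 for rho or 1.80e-05 for r over all libraries stands for it. The acinar score fell as the hormone score rose (rho = -0.360, p = 0.00042, adjusted p = 0.000756; r = -0.294, p = 0.00352, adjusted p = 0.00528), with r = -0.282 without the same 2 libraries and rho = -0.492 and -0.487 at numbers of 50 or lower and above 50. With 5 principal components removed it did not pass (rho = -0.105, adjusted p = 0.375), and without libraries above 25% acinar counts rho was -0.236. With beta cell identity the rank correlation passed (rho = -0.321, p = 0.00169, adjusted p = 0.00277) and the linear one did not (r = -0.186, p = 0.0706, adjusted p = 0.0978; -0.167 without 2 libraries). That relation passed above number 50 (rho = -0.628) and not at 50 or lower (rho = -0.119, adjusted p = 0.538) or with 5 principal components removed (rho = -0.0420, adjusted p = 0.725). Of the 18 relations computed, 11 passed in Spearman's test, 7 positive and 4 negative. When scores were shifted along the library numbers, which keeps neighbouring libraries together, 9 passed, and acinar with hormone genes and beta cell identity with mitochondrially encoded genes did not (adjusted p = 0.0517 each). Libraries with nearby numbers were alike, so the permutation p-values, which shuffle single libraries, are too small, and the smallest p such shifts can give is 0.0105. Shifts do not keep together libraries that are alike at distant numbers, so their p-values may be too small as well.

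Beta cell identity genes were lower where genes normally kept low in beta cells were higher. This was the strongest negative relation (rho = -0.780, adjusted p = 2.57e-05; r = -0.839, adjusted p = 1.80e-05), with r = -0.797 without libraries 97 and 100, and rho = -0.577 and -0.880 at numbers of 50 or lower and above 50. With 5 principal components removed rho was -0.368. Libraries 97, 99 and 100, with the highest scores of genes normally low in beta cells (2.48, 1.95 and 2.26), also had the highest macrophage (3.31, 3.14 and 3.26) and lymphocyte scores (3.23, 2.87 and 2.86). Aldh1a3, the member with the widest range, had only 1.98, 1.05 and 1.98 CPM there, against 220 CPM in library 90. Levels were measured in whole islets, so a different mix of cells cannot be told apart here from a change within beta cells. Beta cell identity also fell as macrophage genes rose (rho = -0.422, p = 5e-05, adjusted p = 0.000112; r = -0.803, adjusted p = 1.80e-05), with r = -0.712 without libraries 97 and 100. This relation passed above number 50 (rho = -0.613), but not at 50 or lower (rho = -0.0965, adjusted p = 0.616) or without libraries numbered above 90 (rho = -0.216, adjusted p = 0.0764). With 5 principal components removed its sign turned and it did not pass (rho = 0.0875, adjusted p = 0.445). With mitochondrially encoded genes the score rose (rho = 0.378, p = 0.0002, adjusted p = 0.0004; r = 0.437, adjusted p = 1.80e-05), with r = 0.387 without libraries 97 and 100. There rho was 0.428 above number 50 and 0.257 at 50 or lower, where it did not pass (adjusted p = 0.134), nor did it with 5 principal components removed (rho = 0.166, adjusted p = 0.14). Without libraries numbered above 90 rho was 0.243.

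**Figure D4:**
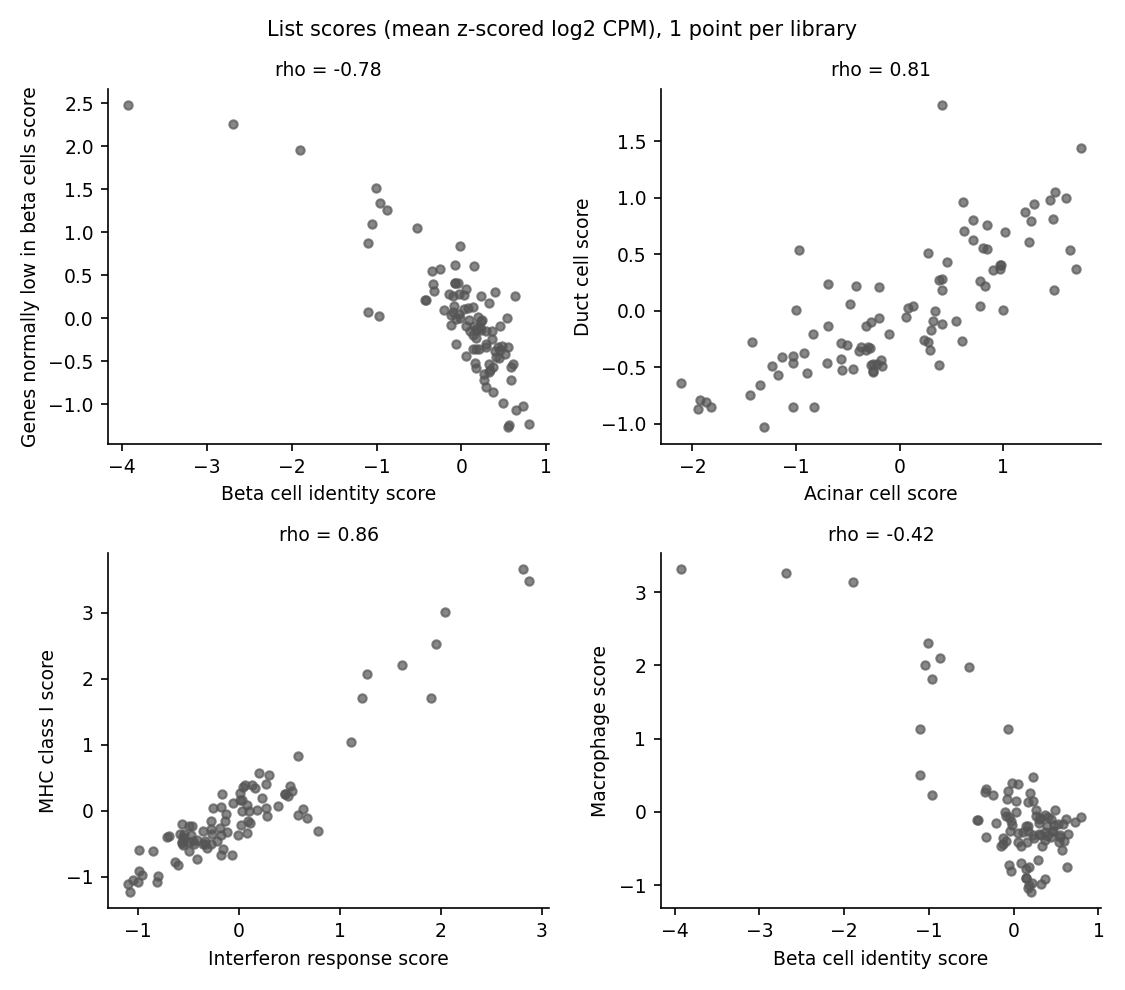
List scores, the mean z-scored log2 CPM of the members, plotted against each other with 1 point per library (95 libraries); Spearman's rho is given above each panel. Beta cell identity fell as genes normally low in beta cells rose (rho = -0.780), acinar and duct scores rose together (0.809), as did interferon and MHC class I scores (0.858), and the panel of beta cell identity with macrophage genes (-0.422) includes libraries 97, 99 and 100, with beta cell identity scores of -3.93, -1.90 and -2.69.

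Immune gene groups rose together. Interferon response and MHC class I genes gave the highest rank correlation of the family (rho = 0.858, adjusted p = 2.57e-05; r = 0.935, adjusted p = 1.80e-05). Without libraries 97 and 100 r was 0.906, and rho was 0.885 and 0.810 at library numbers of 50 or lower and above 50. Macrophage genes rose with MHC class II genes (rho = 0.70, adjusted p = 2.57e-05; r = 0.936, adjusted p = 1.80e-05), with r = 0.908 without libraries 97 and 100 and rho = 0.630 and 0.772 in the ranges of numbers. They also rose with lymphocyte genes (rho = 0.547, adjusted p = 2.57e-05; r = 0.839, adjusted p = 1.80e-05), with r = 0.783 without these libraries. The macrophage and lymphocyte scores were related above number 50 (rho = 0.735) and did not pass at 50 or lower (rho = 0.257, adjusted p = 0.134). With 5 principal components removed that rho was -0.273 and passed in the opposite direction (adjusted p = 0.013).

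Unfolded protein response genes rose with cholesterol synthesis genes, whose enzymes sit largely in the endoplasmic reticulum (rho = 0.447, adjusted p = 2.57e-05; r = 0.465, adjusted p = 1.80e-05). Without libraries 78 and 79 r was 0.447, and rho was 0.544 and 0.394 at numbers of 50 or lower and above 50. Endothelial genes rose with fibroblast and stellate genes (rho = 0.552, adjusted p = 2.57e-05; r = 0.491, adjusted p = 1.80e-05), with r = 0.460 without libraries 46 and 5. There rho was 0.825 at numbers of 50 or lower and 0.182 above 50, where it did not pass (adjusted p = 0.266), and 0.353 with 5 principal components removed.

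The remaining 7 relations did not pass in Spearman's test. Beta cell identity with proliferation had rho = -0.202 (p = 0.0502, adjusted p = 0.0695), although r was -0.647 (adjusted p = 1.80e-05) and -0.430 without libraries 97 and 100. Its rho was -0.00655 without libraries numbered above 90, and it passed above number 50 (-0.309, adjusted p = 0.0469), with the acinar score removed (-0.274, adjusted p = 0.0102) and with median scores (-0.226, adjusted p = 0.0416). Beta with alpha cell genes had rho = 0.0973 (p = 0.347, adjusted p = 0.417), with r = 0.356 (p = 0.00048, adjusted p = 0.000785) and 0.188 without libraries 97 and 100. It passed above number 50 (rho = 0.357, adjusted p = 0.0229) and had rho = -0.0508 without libraries numbered above 90. Macrophage genes with Fabp4 had rho = 0.203 (p = 0.0485, adjusted p = 0.0695) and r = 0.0563 (p = 0.588, adjusted p = 0.706). It passed with the deposited variance-stabilised values (rho = 0.220, adjusted p = 0.0479) and without the 10 libraries of lowest totals (0.232, adjusted p = 0.0497). It passed in the opposite direction above number 50 (-0.354, adjusted p = 0.0237) and with 5 principal components removed (-0.406, adjusted p = 0.000288). Beta cell identity with the unfolded protein response had rho = -0.125 (p = 0.225, adjusted p = 0.289) and r = 0.0295 (p = 0.780, adjusted p = 0.826). The unfolded protein response with proliferation had rho = -0.0904 (p = 0.385, adjusted p = 0.433) and r = -0.147 (p = 0.156, adjusted p = 0.201). With 5 principal components removed both of these relations with the unfolded protein response passed, at rho = -0.232 (adjusted p = 0.0357) and -0.268 (adjusted p = 0.0155). Acinar with immediate early genes had rho = 0.0531 (p = 0.611, adjusted p = 0.611) and r = 0.0124 (p = 0.905, adjusted p = 0.905), and passed with 5 principal components removed (rho = 0.364, adjusted p = 0.000874). Acinar with macrophage scores had rho = -0.0683 (p = 0.508, adjusted p = 0.538) and r = 0.0392 (p = 0.703, adjusted p = 0.791). Their rho was -0.380 at numbers of 50 or lower (adjusted p = 0.0182) and 0.313 above 50 (adjusted p = 0.0446), with -0.350 once 5 principal components were removed (adjusted p = 0.00112), and the difference between the ranges was not tested.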

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

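Leaving out libraries numbered above 90 or those above 25% acinar counts, and shifting scores along the library numbers, were chosen after the results were seen; the other alternatives were planned. Genes above a coefficient of variation of 50% numbered 3074 to 3875 under 6 alternatives and 7713 without the low-count filter, which adds genes of low counts. The number of coherent lists was 16 to 21 and that of relations past the threshold 8 to 14. Of the list values under alternatives 242 kept their direction and side of the threshold, 6 lost the call and 2 gained it. Of the relation values 201 kept both, 9 lost the call, 11 gained it and 8 changed sign. With 5 principal components removed these were macrophage with lymphocyte genes (rho = -0.2734, adjusted p = 0.013), macrophage genes with Fabp4 (rho = -0.4057, adjusted p = 0.000288) and beta cell identity with macrophage genes (rho = 0.08747, adjusted p = 0.445). Among libraries numbered above 50 they were macrophage genes with Fabp4 (rho = -0.3537) and acinar with macrophage genes (rho = 0.3131), the latter also with median scores (rho = 0.01571). Without libraries numbered above 90 they were acinar with immediate early genes (rho = -0.05744) and beta with alpha cell genes (rho = -0.05083). The causes were not tested. Removal of 5 components also ended acinar with beta cell identity (rho = -0.04195, adjusted p = 0.725), acinar with hormone genes (rho = -0.1047, adjusted p = 0.375) and beta cell identity with mitochondrially encoded genes (rho = 0.1657, adjusted p = 0.14). Plain totals shifted all genes of a library by -1.11 to 0.36 log2, DESeq2 size factors by 0.00 to 0.05, and totals without acinar and hormone genes by 0.46 to 0.50. The medians of the 10 most abundant genes moved by less than their spread over libraries under plain totals and DESeq2 size factors. Genes below the low-count filter were not described at these depths.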

Other observations

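The test of mt-Co2 summed with its copies, both tests of blood, and the bootstrap and Wilson intervals were chosen only after the results were seen. Libraries 97 to 100 held high levels of B and T cell genes. Cd3e, a T cell receptor component, had 68.4, 25.1, 33.3 and 38.8 CPM in libraries 97, 98, 99 and 100, against a median of 0.0973 over all libraries. It was also raised, to lower levels, in other libraries, among them 91, 92 and 93 (15.4, 18.8 and 9.85 CPM). Those libraries had Cd74 at 1280, 1619 and 1143 CPM. Ighm, the heavy chain of immunoglobulin M, had 2211, 845, 2609 and 727 CPM, and libraries 39, 74, 91, 92 and 93 had 566, 1312, 879, 1832 and 424 CPM. In library 97 Mki67 (97.1 CPM), Lyz2 (1347 CPM) and Cd74 (3749 CPM) were also at their highest, and Ins2 at its lowest CPM (35013). As a share of counts, Ins2 was lowest in library 69 (3.95%), with 4.51% in library 97. Library 90 had the highest Aldh1a3 (220 CPM), followed by libraries 86 (103 CPM), 89 (98.6 CPM) and 88 (58.3 CPM), and also the highest Igha (338 CPM) and H2-Ea-ps (112 CPM).

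Single genes fell into separated levels. Ddx3y, Uty, Kdm5d and Eif2s3y on chromosome Y were low in the 48 libraries with high Xist and high in the other 47, with the sum of their CPM at 1.51 or lower and at 125 or higher. Library 90 had an intermediate Xist value, 47.5 CPM, beside Ddx3y at 57.8 CPM, and whether it is a mixed or mislabelled sample was not tested, which also bears on its Aldh1a3, Igha and H2-Ea-ps values. Dhrs7c, a dehydrogenase/reductase gene on chromosome 11 (67798187 to 67816002), had 168, 171, 141, 198, 162, 135, 167, 139 and 104 CPM in libraries 66, 67, 68, 69, 70, 72, 73, 74 and 75, and at most 1.42 CPM elsewhere. In the same 9 libraries and in libraries 9 to 13, 15, 16 and 40 to 48, H2-Eb1 lay between 0.622 and 3.85 CPM, with 20.0 CPM or more elsewhere. Gm13341 had 175 to 294 CPM in libraries 1 to 8 and 34 to 39 and at most 0.929 CPM elsewhere. Gm9385 (gap 5.33 log2), Gm3244 (5.32), Rps15-ps2 (5.28), Rpl36a-ps2 (5.16) and Rpl9-ps6 (5.16) completed the 10 largest gaps. Nnt, a mitochondrial transhydrogenase gene, showed no such gap (largest 0.21 log2) and ran from 20.8 to 86.3 CPM. It still differed between runs of library numbers. In libraries 17 to 24 it lay between 20.9 and 25.4 CPM, and in libraries 49 to 58 between 20.8 and 33.2 CPM. Elsewhere it was 37.6 CPM or more, except in libraries 2 (24.8 CPM) and 7 (28.6 CPM).

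In all, 66 of 15841 genes had a gap of 3 log2 or more with at least 6 libraries on each side, and 36 of them were pseudogenes (54.5% against 2.78% of genes searched; Fisher's exact odds ratio 45.7, p = 5.8e-39, across genes, which are not independent). Depth is argued against as the main cause, since the median absolute rho of these genes with library totals was 0.1198, although it was lower over all genes, 0.0803. Reads shared between similar genes may explain part: 31.82% of the 44 with a partner fell as the partners rose, above the highest of 1000 shuffles (22.7%) but below the preset 50%, so how large a part stays open. They are argued against as the whole cause: 30.3% of the 66 (Wilson interval 20.6% to 42.2%) lacked a partner in the annotation, against the preset 10%, and 18.18%, Ddx3y, Uty, Eif2s3y and Dhrs7c among them, shared under 1% of their words with any annotated gene, although this missed the preset 25%. For mt-Co2, at 22.6 to 35.8 CPM in libraries 1 to 8, 34 to 39, 66 to 70 and 72 to 75 and at 807 to 1814 CPM elsewhere, the sum with Gm28661 and Gm13341 kept 14.83% of the log2 range, against 33.9% or more in 10000 shuffles and 32.5% or more in 94 shifts of the copies along the library numbers, so division of reads among copies is a candidate explanation there. Some of the splits fell on the same libraries: mt-Co2 was low in those with high Gm13341 and in those with high Dhrs7c. The 66 genes are therefore not separate observations. A strain variant against the reference stays open, and no biological explanation was tested, since strain and sex are not given per library. Sex is a candidate explanation for Ddx3y, Uty, Kdm5d and Eif2s3y, since Xist, which silences an X chromosome in females, ran opposite to them. In 48 libraries Xist was high and these genes low, in 47 the reverse, and 0 had both high or both low. The library with an intermediate Xist value was counted among the 47.

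Acinar and beta cell identity scores were inversely related by rank (rho = -0.321) but not past the threshold by r (-0.186, adjusted p = 0.0978), and the rank call was lost at library numbers of 50 or lower (rho = -0.119) and with 5 principal components removed (-0.04195). Whether a few genes taking most of the counts set this relation stays open: rho was -0.337 without acinar and hormone genes in the totals, but that scaling moved every library by nearly the same 0.46 to 0.50 log2, so it decides nothing. Depth stays open as well: the acinar score had rho = 0.2071 with library totals (0.0130 to 0.388), just above the preset bound of 0.2. Acinar cells carried over with the islets are a candidate source, since the median rho of the members with the rest of their list was 0.9806, with 0.95 for the transcription factor gene Ptf1a and 0.991 for Pnlip, although a change of expression within cells was not excluded. No biological explanation was tested.

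Lymphocyte transcripts varied together. Carry-over with exocrine tissue and library depth are argued against as causes shared by all libraries. The lymphocyte score had rho = 0.06076 with the acinar score (bootstrap interval -0.133 to 0.243, below the preset 0.3) and rho = -0.03651 with library totals (-0.260 to 0.180). A rho over all libraries can hide opposite relations within ranges of library numbers, which are not given for these scores. Carry-over in some libraries stays open. Acinar shares were 3.98% and 3.78% in libraries 97 and 99, with the highest lymphocyte shares, and 32.2% and 28.5% in libraries 93 and 95. Whole blood is argued against as the source of the highest shares, since haemoglobin transcripts outweigh those of lymphocytes in blood and 27 libraries had a larger share in the lymphocyte list, with erythroid shares of 0.00607%, 0.00657%, 0.00808% and 0.00454% in libraries 97 to 100. In some of the 27, Ighm was high and Cd3e low, as in libraries 39 (566 and 0.122 CPM) and 24 (132 and 0.143 CPM). The count of 27 therefore rests in part on 1 gene, while both genes were high in libraries 97 to 100. Blood may add a part, since the lymphocyte and erythroid scores had rho = 0.3 (0.0931 to 0.473), at the bound set for that test. Lymph nodes taken with the islets, and immune cells within them, were not tested and stay open, and no biological explanation was tested.

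Genes under 100 kb apart had a mean absolute rho of 0.236 against 0.206 on different chromosomes, and 70.99% of this excess was left without overlapping pairs and pairs with a shared symbol stem. Libraries next to each other in number had a mean correlation of 0.6241, against at most 0.105 in 10000 shuffled orders, so bootstrap intervals, which treat libraries as independent, are too narrow.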
